A study of Mus musculus with 169 samples.

How the data were processed

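Expression was measured in mice of 3 genotypes at the progranulin gene (Grn): wild type (WT), heterozygous (het) and knockout (KO). Bead arrays (Illumina) measured cortex, hippocampus and cerebellum of WT, het and KO mice of 2, 6, 9, 12 and 18 months and of 1 WT and 1 KO mouse of 16 months (no KO cerebellum), with 154 arrays from 57 mice. Single-color Agilent arrays measured microglia sorted from WT and KO mice of 4 and 16 months, with 15 arrays. Per the labels' protocols, brain RNA was extracted with Trizol, cleaned on RNeasy columns with DNase and labeled with biotin. Microglia came from Percoll gradients and were sorted by CD11b, CD45 and Ly6G, per the labels. The brain mice were of mixed strain and the microglia mice were on a C57B/6J background, per the labels. Per the series description, the submitters left out 9 brain samples as outliers and 1 microglia sample. The 9 unused pairs of columns in the bead array table were not used here.

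The deposited bead array table gives the intensity of 25697 probes per array, not normalized, and for each a detection p-value; per the file headers these are the 2 columns of each array. The Agilent processed signal is the intensity of a spot after background subtraction, per the file headers, from Feature Extraction 10.7.3.1 on array design 028005. The submitters' processing notes also name R 2.15.3. Checked on the values, the deposited signal of the 4-month arrays also differed from the background-subtracted intensity by a factor that varied with position on the slide, whereas that of the 16-month arrays did not. Comparisons within an age are within 1 kind of signal, and an alternative that started from the median spot signals avoided the difference.

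For microglia, each array's processed signal was divided by its 75th percentile and put on the log2 scale. Repeat spots of 1 probe were averaged without outlier spots, and signals below a floor of 0.0325 times the 75th percentile (-4.94 on the log2 scale) were set to that floor, so a fitted difference for a gene at the floor in a whole group is a lower bound on its size. Of 55681 probes, 45616 were well above background on at least 3 arrays. For each gene the probe with the highest mean was used, which left 31927 features, 17798 of them with a gene symbol. The files gave a symbol for 26582 probes and 20145 symbols.

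The log2 difference between WT arrays 1 and 2 at 16 months had a scaled median absolute deviation of 0.123 over 21979 probes. Between arrays 3 and 4 it was 0.094, and in the other pairs of arrays within a group 0.383 to 1.28. The difference between 2 repeat spots of a probe within 1 array had a standard deviation of 0.164 to 0.263. Arrays 1 and 2 were therefore averaged as 1 replicate, and arrays 3 and 4 as another. The fit held 13 replicates: 4 WT and 3 KO at 4 months, 2 WT and 4 KO at 16 months. Each age was on its own slide, so age and slide cannot be told apart. Genotypes lay in different positions on a slide, so genotype and position cannot be told apart either.

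WT and KO arrays of an age share replicate numbers in the labels, which do not say what a number stands for. The correlation of deviations from the group means was -0.042 to -0.036 in the 3 same-numbered pairs at 4 months and 0 of 3 KO arrays there correlated best with their own number. At 16 months it was 0.115 to 0.124 in the 4 same-numbered pairs. Different numbers within 1 and 2 or within 3 and 4 gave 0.081 to 0.133. Numbers across these sets gave -0.149 to -0.09. Because the 4 WT arrays there stand for 2 samples, this pattern rests on a single WT difference and cannot show whether numbers pair samples. The fit without a replicate block was kept as the main one. The block, which took 1 and 2 together and 3 and 4 together at 16 months, was an alternative.

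One linear model over the 4 microglia groups was fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with version 1.17.8 of data.table for reading. Contrasts were KO minus WT at each age, the difference between those changes (interaction) and WT at 16 minus 4 months. Every adjusted p of a single gene or probe is from limma's moderated test, two-sided, and those of gene lists are from camera or fry, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are log2 values with standard error (SE).

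Bead array intensities were background-corrected and quantile-normalized together with limma's neqc (offset 16). Probes with a detection p-value under 0.05 on at least 3 arrays of a region were tested in it. Within each region, limma was fitted with genotype, age as a factor and sex. A KO-by-month term gave the slope of the KO minus WT difference, and a model with 1 mean per genotype and age gave the difference at single ages. Sex entered as a number, set midway where the 12-month labels gave none. The 16-month age had 1 WT and 1 KO mouse and was left out of the fits by age. KO effects were compared between regions over all arrays with mouse as a random block (correlation 0.0667) and 17732 probes. Probe identifiers of the bead arrays carry no gene names in the sources used here, so gene lists were not tested in brain and the Grn probe could not be named to check genotype labels. With no gene names every probe was tested there, so the alternative of every probe in place of 1 per gene changes nothing.

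Before the data were examined, 28 gene lists were fixed. They cover complement, lysosome, disease-associated microglia, homeostatic microglia, type I interferon, cytokines and NF-kB, antigen presentation, cholesterol synthesis, lipid transport and storage, synapse, immediate early genes, cell cycle, unfolded protein and amino acid stress, and sex-linked genes. Marker lists cover neuron, inhibitory neuron, astrocyte, reactive astrocyte, oligodendrocyte and myelin, endothelium, choroid plexus, striatum, monocyte, border macrophage, neutrophil, T and NK cell, B cell and red blood cell. Genes that stand in more than 1 list include Apoe, B2m, Ccl3, Cd63, Cd68, Ch25h, Ctsb, Ctsd, Ctsz, Cxcl10, Itgax and Lpl. Results of a few single genes are not reported. Each list was tested against all other features with limma's camera (preset correlation 0.01), adjusted over the lists. Camera with a correlation estimated from the data and fry, which tests whether the members move one way on balance, were run beside it.

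The design, the alternatives and the rule for named genes were also fixed before the data were examined. In each microglia comparison Grn, C1qa, C1qb, C1qc and C3 are always named. Up to 3 members of each list with the smallest adjusted p among those past the threshold are named, or 2 members where a list was called and no gene passed. Also named are the 6 largest rises and 6 largest falls with a symbol, without predicted genes, where all KO arrays lay on one side of all WT arrays of that age. In brain, the 2 identifiers that rose and the 2 that fell and that are printed were chosen after their values were seen.

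The models were tested on simulated data with known changes. At 16 months 82% of simulated log2 changes of 4 were recovered and 32% of changes of 2, with 7 false calls among 31482 features. The figures were 87% and 42% at 4 months and 57% and 12% for the interaction. In brain, changes of 1 were recovered in 96 to 100% of cases over all ages, in 66 to 94% at 2 months and in 45 to 63% at 18 months. False calls were 0 to 13 over 22 comparisons. Every microglia group was simulated with a common spread, whereas real arrays of a group differed by more at 16 than at 4 months. The simulated false calls therefore do not measure the error of the 16-month test. The number of arrays limits the precision.

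Alternatives for microglia were quantile normalization, a 75th percentile over probes well above background on all arrays, no filter, a filter on all 15 arrays, every probe, a fit of the groups compared alone, a replicate block and each replicate left out. The planned background correction by normexp (offset 50) called for mean spot signals, which the files do not hold, so it was run on median signals. For brain they were log2 and quantile normalization without background correction, normalization within a region, no filter, a stricter filter, no sex term, ages left out, no mouse block, the compared groups alone and each replicate left out. A chip block was not run because neither columns nor labels name a chip. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.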

Results

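The series measured gene expression in mice with and without progranulin, a secreted and lysosomal glycoprotein encoded by Grn. Microglia were sorted from WT and KO mice of 4 and 16 months, with 4 WT and 3 KO arrays at 4 months and 4 WT and 4 KO arrays at 16 months. The 4 WT arrays at 16 months matched in pairs more closely than repeat spots do and counted as 2 replicates. The 75th percentile of the processed signal was 1306 to 1649 on WT and 1072 to 1752 on KO arrays at 4 months, and 1010 to 1511 on WT and 507 to 1037 on KO arrays at 16 months. Probes well above background made up 70.3 to 76.5%, 66.4 to 73%, 64.6 to 69.8% and 54.2 to 62.7% of all probes in the same 4 groups, and 0 spots were saturated. The 4 KO replicates at 16 months stood apart on the first principal component, which held 62.2% of the variance (212.6 to 260, against -156 to -11 in the other groups). Brain tissue comprised 55 cortex arrays (19 WT, 17 het, 19 KO), 51 hippocampus arrays (16 WT, 17 het, 18 KO) and 48 cerebellum arrays (16 WT, 15 het, 17 KO). Between 47.5 and 55.5% of bead array probes were detected per array. Median intensity was 79.7 to 114 on the 2-month arrays and 127.3 to 352 at the other ages.

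Grn was lost from KO microglia at both ages. At 4 months its level (log2 of the signal over the array's 75th percentile, as for all microglia levels) was 6.25 ± 0.086 in WT (SD, n = 4) and -2.77 ± 0.66 in KO (SD, n = 3), a difference of -9.03 (SE 0.29, adjusted p = 2.88e-07) on probe A_51_P192800. At 16 months it was 5.04 ± 0.60 in WT (SD, n = 2) and at background on all 4 KO arrays, which made it at least 1010-fold lower in KO (adjusted p = 3.75e-07). The difference between the 2 ages was -0.95 (SE 0.43, adjusted p = 0.165), and the value is limited by the background on the KO arrays. Every gene named below as risen or fallen in microglia had all replicates of one group on one side of all replicates of the other, except that this was not examined for genes named after their values were seen.

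The comparison of KO with WT microglia at 16 months asked how aged microglia differ without progranulin, with complement as the pathway named in the study's title. Homeostatic microglia genes, which mark resting microglia, were lower in KO, where a lower share of microglia was not excluded as the cause. Of 17 measured, 16 fell, and 16 fell adjusted over the list alone, with a median of -3.23 relative to all features (camera adjusted p = 2.39e-07, adjusted p = 0.715 with an estimated correlation). Tmem119, a surface marker of resident microglia, fell by 3.77 (SE 0.53, adjusted p = 0.000615), Selplg by 4.93 (SE 0.68, adjusted p = 0.000584) and Siglech by 1.71 (SE 0.26, adjusted p = 0.000973). Gpnmb, a glycoprotein of lipid-laden phagocytes, rose by 7.64 (SE 1.07, adjusted p = 0.00061) from a WT level above background on 1 of 4 arrays. Apoe, the main lipid carrier of the brain, rose by 1.58 (SE 0.25, adjusted p = 0.00102), and by 0.92 with quantile normalization.

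**Figure D1:**
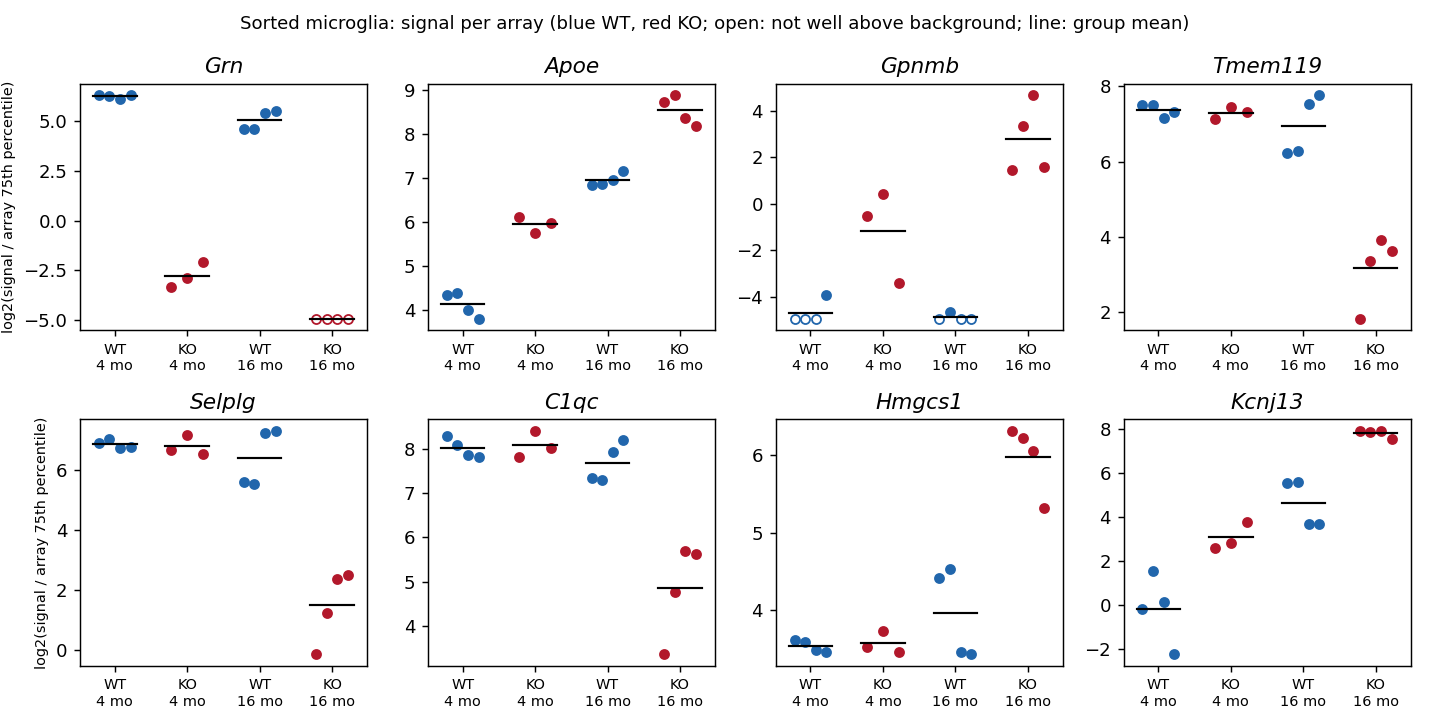
Log2 of the signal over the array's 75th percentile for Grn, Apoe, Gpnmb, Tmem119, Selplg, C1qc, Hmgcs1 and Kcnj13 on each of the 15 microglia arrays by age, with WT in blue, KO in red, open symbols where the signal was not well above background and lines at group means. Grn lay at the floor of -4.94 on all 4 KO arrays at 16 months, and Tmem119 averaged 3.18 in KO against 6.95 in WT at that age.

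Few complement genes passed limma's test at 16 months. C1qc, a chain of the initiator C1q, fell by 2.83 (SE 0.56, adjusted p = 0.00356; 0.0829 in a fit of the 16-month arrays alone). C1qa differed by -0.86 (SE 0.70, adjusted p = 0.38) and C1qb by -0.97 (SE 0.65, adjusted p = 0.278; 0.0415 with a replicate block); without WT replicate 3 and 4 they differed by 0.030 and 0.055. C3, the central component, differed by -1.04 (SE 0.39, adjusted p = 0.0609) and passed with quantile normalization (0.0336). Of the 16 complement genes 1 rose and 3 fell, and 1 and 3 adjusted over the list alone, with a median of -1.25 relative to all features (camera adjusted p = 0.033, adjusted p = 0.715 with an estimated correlation). The falls were C1qc, the receptor subunit Itgax (-2.81, SE 0.46, adjusted p = 0.00135) and its relative Itgam (-1.97, adjusted p = 0.00889; 0.0937 without WT replicate 3 and 4). The rise was Serping1, the C1 inhibitor (2.08), chosen after its value was seen. Camera did not call complement when the 75th percentile was taken over probes detected on all arrays (adjusted p = 0.0561).

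Camera called immediate early, cytokine and NF-kB, and antigen presentation genes lower in KO at 16 months. Of 11 immediate early genes, which respond within minutes to stimulation, 9 fell (10 adjusted over the list alone; median -3.38 relative to all features; camera adjusted p = 1.41e-05, adjusted p = 0.689 with an estimated correlation). Fosb fell by 4.29 (SE 0.52, adjusted p = 0.000306) and Jun by 5.11 (SE 0.71, adjusted p = 0.000574). Of 20 cytokine and NF-kB genes 10 fell (10 adjusted over the list alone; median -2.53 relative to all features; camera adjusted p = 1.41e-05, adjusted p = 0.715 with an estimated correlation). They included Nfkbia, an inhibitor that NF-kB itself induces (-2.34), the chemokine Ccl4 (-1.37; adjusted p = 0.0655 in a fit of the 16-month arrays alone) and Il6 (-5.76, adjusted p = 0.0503 without WT replicate 3 and 4). Of 14 antigen presentation genes 7 fell (7 adjusted over the list alone; median -1.44 relative to all features; camera adjusted p = 0.00222, adjusted p = 0.715 with an estimated correlation). The class II invariant chain Cd74 (-4.41, SE 0.57, adjusted p = 0.000407) and the class II transactivator Ciita (-4.05, SE 0.47, adjusted p = 0.000243) were among them. Of 21 type I interferon genes 2 rose and 6 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0675). Bst2 rose by 1.80 (1.15 with quantile normalization) and Isg15 fell by 2.70.

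Cholesterol synthesis genes were higher in KO at 16 months. Of 21 measured 9 rose and 0 fell (10 rose adjusted over the list alone; median 1.38 relative to all features; camera adjusted p = 0.00421, adjusted p = 0.689 with an estimated correlation). Fdft1, which makes squalene, rose by 3.72 (SE 0.38, adjusted p = 0.000142), Idi1 by 2.49 (SE 0.32, adjusted p = 0.000428) and Hmgcs1 by 2.02 (SE 0.32, adjusted p = 0.0011), the last by 1.33 with quantile normalization and with adjusted p = 0.0521 in a fit of the 16-month arrays alone. Of 12 lipid transport and storage genes 4 rose and 4 fell, also adjusted over the list alone. The fatty acid carrier Fabp5 rose by 3.66 (SE 0.36, adjusted p = 0.00012) and the sterol exporter Abcg1 fell by 2.43 (SE 0.29, adjusted p = 0.000285). That list's median was -0.37, its camera direction was down (adjusted p = 0.946) and its fry direction up (adjusted p = 0.377).

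Lysosomal genes moved both ways. Of 52 measured, 11 rose and 8 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.928, up). The direction was not stable, with 8 rises and 18 falls and a camera direction of down under quantile normalization. Atp6v1a, a subunit of the proton pump, rose by 2.79 (SE 0.27, adjusted p = 0.000123) and the galactosidase Glb1 by 1.51 (SE 0.22, adjusted p = 0.0008), while the lysosomal membrane protein Laptm5 fell by 5.38 (SE 0.81, adjusted p = 0.00086). Of 23 disease-associated microglia genes 4 rose and 6 fell (5 and 6 adjusted over the list alone). Their median was -0.40, their mean 0.00072, the camera direction down (adjusted p = 0.928) and the fry direction up (adjusted p = 0.776).

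Markers of other cell types went both ways in KO at 16 months, with 19 rises and 12 falls among 104 markers in 13 lists, reactive astrocyte genes not counted. Choroid plexus genes, from the epithelium that makes cerebrospinal fluid, rose in 6 of 12 (6 adjusted over the list alone; median 2.39 relative to all features; camera adjusted p = 0.0136, adjusted p = 0.715 with an estimated correlation). Cldn2 rose by 3.39 (SE 0.51, adjusted p = 0.000885), and Kcnj13 by 3.19 (SE 0.85, adjusted p = 0.0156; 0.12 without WT replicate 3 and 4). With quantile normalization 1 choroid plexus gene rose and camera gave adjusted p = 0.0819. Astrocyte genes rose in 2 (Aldh1l1, Sox9) and fell in 1 (Slc1a3) of 10, reactive astrocyte genes in 2 (S1pr3, Vim) and 1 (Cd44) of 10, and neuron genes in 1 (Map2) and 2 (Rbfox3, Slc12a5) of 10. Inhibitory neuron genes rose in 1 (Pvalb) and fell in 1 (Kcnc1, at least 6.85-fold) of 10, endothelium in 2 (Slco1a4, Itm2a) and 2 (Esam, Kdr) of 10, striatum in 2 (Gpr6, Drd2) and 1 (Adora2a) of 7, and oligodendrocyte and myelin in 1 (Mog) and 4 (among them Mag, Ermn and Mobp) of 11. Mobp was at least 10.5-fold lower, but rose by 1.54 on another probe kept by the filter on all 15 arrays. Adjusted over the list alone these counts were the same, except that 0 inhibitory neuron genes rose. The directions of camera and fry differed for striatum (down and up, adjusted p = 0.991 and 0.572). Kdr, Mog and Ermn were named after their values were seen. A replicate block ended the calls of Pvalb, S1pr3, Vim, Esam and Adora2a. Without WT replicate 3 and 4 the adjusted p was 0.0872 for Aldh1l1, 0.12 for Sox9, 0.0897 for Map2, 0.0648 for Itm2a, 0.0527 for Mag and 0.353 for Pvalb. Without WT replicate 1 and 2 it was 0.164 for Cd44, 0.0866 for Slc12a5, 0.142 for Esam, 0.0987 for Drd2, 0.427 for Adora2a, 0.23 for S1pr3 and 0.135 for Vim.

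Blood cell markers gave single calls at 16 months. Vcan rose among 6 monocyte genes, Elane among 9 neutrophil genes, Nkg7 among 6 T and NK cell genes and Hba-a1, an alpha globin, among 3 red blood cell genes (2 adjusted over the list alone; the other counts were the same). Hba-a1 rose by 4.42 (SE 0.86, adjusted p = 0.0034), and Cd79b fell by 3.06 (SE 0.52, adjusted p = 0.00167) among 3 B cell genes; in a fit of the 16-month arrays alone their adjusted p was 0.08 and 0.0623. Without WT replicate 1 and 2 the adjusted p of Vcan was 0.0808 and that of Nkg7 0.201. A replicate block also ended the call of Nkg7. None of 7 border macrophage genes passed limma's test, and their median was -0.89 relative to all features. Of 18 synapse genes 1 rose (Homer1) and 5 fell (among them Syn1, Shank3, Gria2 and Camk2a), also adjusted over the list alone (camera adjusted p = 0.318), with Homer1 and Camk2a named after their values were seen. Syn1 fell by 2.89 (SE 0.58, adjusted p = 0.00369; 0.055 in a fit of the 16-month arrays alone). Gria2 was at least 3.51-fold lower, and did not pass without WT replicate 1 and 2. Single genes fell in cell cycle (Bub1, at least 14.5-fold, of 9), unfolded protein and amino acid stress (Atf4, -1.51, of 10; adjusted p = 0.0859 without WT replicate 3 and 4) and sex-linked genes (Kdm5d, -5.43, of 5), each also adjusted over the list alone. The labels do not give the sex of the microglia mice.

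Across all features at 16 months, 10988 of 31925 passed limma's test, 6154 higher and 4834 lower (56.0% higher), and 6360 of them had a symbol. The median of all features was 0.12. The largest rises of genes with a symbol besides Gpnmb were Epha4, an ephrin receptor (7.17, SE 0.69), Cdo1 (6.36), Tcerg1l (at least 61.7-fold), Slc16a12 (5.78) and Fam13c (5.65). Fam13c reversed to -2.05 on another probe without KO replicate 1, 3 or 4. Besides Grn the largest falls were the receptors Tlr12 (-7.69, SE 0.96), Clec4a2 (-6.66) and Clec5a (-6.46), Sema4d (-6.35) and Mdfi (-6.34). The share of rises was 42.9% when the 75th percentile was taken over probes detected on all arrays and 64.6% among probes above background on all 15 arrays, and 3449 features passed in a fit of the 16-month arrays alone. Genes named here that did not pass in that fit had an adjusted p from 0.0518 (Map2) to 0.147 (Esam), and Slc1a3 (0.107), Slco1a4 (0.0715), Shank3 (0.103), Gpr6 (0.0785), Slc16a12 (0.064) and Fam13c (0.0611) were among them.

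**Figure D2:**
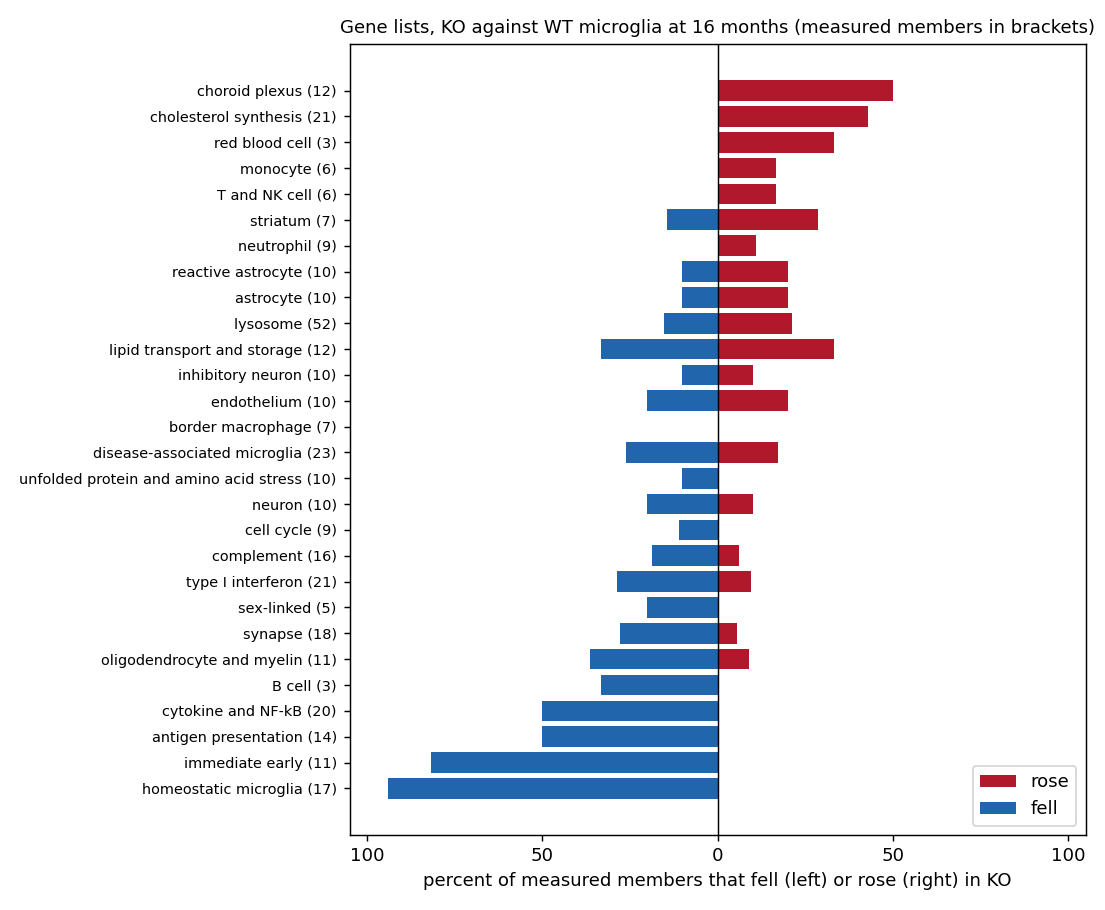
Percent of the measured members of each of the 28 gene lists that fell (left) or rose (right) in KO against WT microglia at 16 months by limma's test. In homeostatic microglia 16 of 17 members fell, and in cholesterol synthesis 9 of 21 rose.

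The same comparison at 4 months asked which of these differences stand in younger mice. Besides Grn, Apoe rose by 1.82 (SE 0.22, adjusted p = 0.0358) and Npr3, a natriuretic peptide receptor, by 3.90 (SE 0.46, adjusted p = 0.0358), from a WT level above background on 1 of 4 arrays. Zfp459 rose by 2.67 (SE 0.33, adjusted p = 0.0382) and Acvr1c, an activin receptor, fell by 2.54 (SE 0.32, adjusted p = 0.0382). None of these complement genes passed limma's test at 4 months. C1qa differed by -0.39 (SE 0.62, adjusted p = 1), C1qb by -0.23 (SE 0.57, adjusted p = 1), C1qc by 0.07 (SE 0.49, adjusted p = 1; -0.064 with quantile normalization) and C3 by 1.64 (SE 0.34, adjusted p = 0.234). Choroid plexus genes were higher in KO as a group, with a median of 3.05 (camera adjusted p = 3.58e-22, adjusted p = 0.178 with an estimated correlation; fry adjusted p = 0.0481). Of 12, 0 passed limma's test over all features and 12 adjusted over the list alone. Kl was higher by 4.14 (SE 0.73, adjusted p = 0.149) and Aqp1 by 3.61 (SE 0.71, adjusted p = 0.2).

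Other lists called by camera at 4 months lay higher in KO. Of 23 disease-associated microglia genes 1 rose, which was Apoe, and 5 adjusted over the list alone (median 0.56, camera adjusted p = 2.24e-08, adjusted p = 0.275 with an estimated correlation). For 52 lysosomal genes 0 rose, and 0 adjusted over the list alone (median 0.23, camera adjusted p = 2.72e-04, adjusted p = 0.574 with an estimated correlation), and Atp6v1a differed by 0.88 (adjusted p = 0.432) and Glb1 by 0.53 (adjusted p = 0.715). For 12 lipid transport and storage genes 1 rose, and 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.027, adjusted p = 0.275 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0848). For 9 neutrophil genes 0 rose, and 0 adjusted over the list alone (median 1.46, camera adjusted p = 0.00934, adjusted p = 0.55 with an estimated correlation), and Cxcr2 differed by 0.94 (adjusted p = 0.837). With a replicate block camera also called cell cycle (adjusted p = 0.0398). In all, 8 of 31923 features passed limma's test, 5 higher and 3 lower, with 1927 at an unadjusted p under 0.05. The 3 without a gene symbol were AK042795 (2.41), AK081233 (-2.35) and 1 intergenic feature on chromosome 10 (1.28), chosen after their values were seen. With a replicate block 1 feature passed, Apoe having adjusted p = 0.312; 0 passed among probes above background on all 15 arrays, with 751 at an unadjusted p under 0.05. Leaving out any 1 replicate of the 4-month arrays ended the call of Apoe (adjusted p = 0.0519 to 0.102), and 3 to 10 features passed. With quantile normalization the adjusted p was 0.078 for Npr3, 0.0768 for Zfp459 and 0.0864 for Acvr1c, and most replicates ended each of these calls when left out, with adjusted p up to 0.104, 0.1 and 0.139. Of the 8 features, 5 passed in the same direction at 16 months, Grn among them, and 0 in the opposite one. The arrays of that age are other samples, but 10988 of all 31925 features passed there. Both tests also share each feature's estimate of the spread, so they are not independent.

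The interaction asked whether the KO change at 16 months differed from that at 4 months, and 4263 of 31922 features passed limma's test, 2174 with a more positive and 2089 with a more negative change at 16 months. The changes of C3 (difference -2.68, SE 0.52, adjusted p = 0.0097) and Itgax (difference -4.31, adjusted p = 0.0031) were more negative at 16 months. C1qc differed by -2.90 (SE 0.75, adjusted p = 0.0296), and 7 replicates ended that call when left out, with WT replicate 3 and 4 giving the highest adjusted p (0.0905). C1qa differed by -0.47 (SE 0.93, adjusted p = 0.772) and C1qb by -0.75 (SE 0.87, adjusted p = 0.604). The homeostatic genes Tmem119 (-3.69, SE 0.70, adjusted p = 0.00941) and Selplg (-4.85, SE 0.91, adjusted p = 0.00873), Cd74 (-4.87, SE 0.76, adjusted p = 0.00417) and Fosb (-4.26, SE 0.70, adjusted p = 0.00519) had more negative changes at 16 months. Fdft1 (3.25, SE 0.50, adjusted p = 0.00411) and Idi1 (2.31, SE 0.43, adjusted p = 0.00855) had more positive ones, as did Bst2 (1.95) and Atp6v1a (1.91; 1.24 and adjusted p = 0.0796 with quantile normalization).

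By list, camera called 7 of 28 for the interaction, and the estimated correlation ended each call. More negative changes stood in 3 of 16 complement genes (adjusted p = 0.00792, adjusted p = 0.53 with an estimated correlation), 10 of 17 homeostatic microglia genes (adjusted p = 5.87e-08, adjusted p = 0.53 with an estimated correlation) and 8 of 20 cytokine and NF-kB genes (adjusted p = 5.45e-06, adjusted p = 0.53 with an estimated correlation). They also stood in 3 of 14 antigen presentation genes (adjusted p = 0.0017, adjusted p = 0.53 with an estimated correlation), 7 of 11 immediate early genes (adjusted p = 1.57e-05, adjusted p = 0.53 with an estimated correlation) and 1 of 9 cell cycle genes (adjusted p = 0.0217, adjusted p = 0.624 with an estimated correlation). More positive ones stood in 5 of 21 cholesterol synthesis genes (adjusted p = 0.0133, adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone these counts were 4, 14, 9, 3, 8, 1 and 8. Medians relative to all features, which had a median of 0.17, ran from -3.36 for homeostatic microglia to 1.24 for cholesterol synthesis. The disease-associated list gave adjusted p = 0.0577 and passed with quantile normalization (0.00785) and with a replicate block (0.0348). With a replicate block 1957 features passed. Leaving out KO replicate 3 at 4 months left 2435 and KO replicate 1 left 2775. The share of more positive changes was 51%, and 39.1% with a 75th percentile over probes detected on all arrays.

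The largest positive interaction values among genes with a symbol were those of Epha4 (7.63), Meis2 (6.12), Ddit4l (5.54) and Timmdc1 (5.53), leaving aside Tcerg1l, which was at background on all WT arrays at 16 months. The largest negative ones were those of the secreted Ccdc80 (-8.31), Tlr12 (-7.58), Sema4d (-6.54) and Icosl, a costimulatory ligand (-6.37). Among markers of other cell types Rbfox3 (-4.96, SE 0.62, adjusted p = 0.00189) changed more negatively at 16 months and Map2 (2.89, SE 0.61, adjusted p = 0.014; 0.0661 with a replicate block) more positively, while 0 of 12 choroid plexus genes passed limma's test. The median of the choroid plexus genes was -1.40 relative to all features.

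The comparison of WT microglia at 16 and 4 months asked what aging changes with progranulin present. Border macrophage genes, which mark macrophages of the brain's surfaces, rose in 5 of 7 (7 adjusted over the list alone) with a median of 5.22 relative to all features (camera adjusted p = 8.47e-10, adjusted p = 0.00301 with an estimated correlation). They were Ms4a7 (6.20, SE 0.99, adjusted p = 0.0116; 0.0665 without WT replicate 1 and 2), F13a1, Mrc1, Cbr2 and Pf4, the last 2 named after their values were seen; F13a1 had adjusted p = 0.0661 without WT replicate 1 and 2, and Mrc1 0.0552 without WT replicate 3 and 4. Choroid plexus genes rose in 11 of 12 (12 adjusted over the list alone; median 5.50 relative to all features; camera adjusted p = 4.97e-22, adjusted p = 0.0907 with an estimated correlation), among them Kl (7.09, SE 0.83, adjusted p = 0.00441). Cholesterol synthesis genes lay higher (median 0.69 relative to all features; camera adjusted p = 0.0286, adjusted p = 0.514 with an estimated correlation) with 0 of 21 past limma's test, also adjusted over the list alone; Sqle differed by 2.85 (adjusted p = 0.0613) and Idi1 by 0.90 (adjusted p = 0.171). With a replicate block camera also called cytokine and NF-kB genes (adjusted p = 0.035).

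Apoe rose by 2.82 (SE 0.25, adjusted p = 0.00365) and Cd74 by 4.44 (SE 0.57, adjusted p = 0.00571) between 4 and 16 months in WT. C3 rose by 2.64 (SE 0.39, adjusted p = 0.00923; 0.0703 without WT replicate 1 and 2 at 16 months), while C1qa differed by -0.61 (adjusted p = 0.74), C1qb by -0.45 (adjusted p = 0.802) and C1qc by -0.33 (adjusted p = 0.844), with signs that turned without the same replicate (0.29, 0.58 and 0.046). Grn differed by -1.21 (SE 0.32, adjusted p = 0.0716). The lectin receptor Clec10a rose by 7.69 (SE 1.02, adjusted p = 0.00606), the chemokine Ccl8 by 7.26 (SE 0.96, adjusted p = 0.00606; 0.0501 with a replicate block) and Rin3 fell by 3.19 (SE 0.45, adjusted p = 0.00814; -1.78 with normexp). In all 1106 of 31925 features passed limma's test, 575 higher and 531 lower (52.0% higher), around a median of all features of -0.18, and the share higher was 64.5% with quantile normalization and 75.1% with a 75th percentile over probes detected on all arrays. With a replicate block 433 passed; without WT replicate 1 and 2 at 16 months 329, without replicate 3 and 4 there 3768, and without WT replicate 3 or 4 at 4 months 629 and 648. Age and slide cannot be told apart here. Because border macrophage and choroid plexus genes rose too, a changed mix of sorted cells was not excluded for the genes named here.

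In brain tissue, the comparison of KO with WT over all ages asked what progranulin loss changes in each region. The deepest fall was that of probe ILMN_2595973, by 4.92 in cortex (adjusted p = 2.49e-40), 5.06 in hippocampus (adjusted p = 3.68e-37) and 4.86 in cerebellum (adjusted p = 1.23e-33). It was detected on no KO array and on every WT and het array, so its fall is set by the background. ILMN_1250569 fell by 1.43 in cortex (SE 0.11), 1.34 in hippocampus (SE 0.12) and 1.19 in cerebellum (SE 0.14). ILMN_2496121 rose by 1.21 in cortex (SE 0.097, adjusted p = 1.53e-13), 1.10 in hippocampus (SE 0.070, adjusted p = 4.14e-16) and 1.00 in cerebellum (SE 0.085, adjusted p = 5.71e-11). These 4 identifiers, ILMN_2614655 included, were chosen after their values were seen, and their gene names are not given in the sources used here. Without background correction their differences were smaller, with that of ILMN_2595973 at -2.72 in cortex. The brain mice were of mixed strain, and variants carried along with the targeted locus were not excluded as a source of KO differences.

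Cortex had 124 probes past limma's test (90 higher and 34 lower in KO, of 16770), hippocampus 88 (70 and 18, of 16981) and in cerebellum 97 were higher and 12 lower of 16860. Of the 16026 probes tested in all 3 regions, 40 rose and 6 fell in each region. Cortex and hippocampus shared 43 rises (0.384 by chance for independent lists), cortex and cerebellum 50 (0.533) and hippocampus and cerebellum 48 (0.406), in tissue of the same mice. Falls were shared by 8 probes in each pair of regions (0.0331, 0.0204 and 0.0121 by chance). Without the 12-month arrays 46 probes passed in hippocampus and 61 in cerebellum, and 68 passed in cerebellum with a stricter detection filter.

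The direct test of region differences asked whether the KO change depends on region. Between hippocampus and cortex 0 of 17732 probes passed limma's test (680 at an unadjusted p under 0.05), between cortex and cerebellum 0 (944), and between hippocampus and cerebellum 1 (908), with a lower KO change in hippocampus. Without background correction 1 probe passed between cortex and cerebellum.

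Het mice asked what loss of 1 Grn copy changes. In cortex 5 probes passed limma's test (4 higher and 1 lower than WT), in hippocampus 3 (2 and 1) and in cerebellum 2 (1 and 1), with 971, 1335 and 534 at an unadjusted p under 0.05. ILMN_2595973 fell by 0.96 in cortex (adjusted p = 1.23e-08), 1.02 in hippocampus (adjusted p = 8.92e-09) and 1.06 in cerebellum (adjusted p = 6.03e-08). ILMN_2496121 rose by 0.78 (adjusted p = 2.22e-06), 0.75 (adjusted p = 2.39e-09) and 0.59 (adjusted p = 0.000336) in the same regions. ILMN_1250569 differed by -0.43 in cortex (adjusted p = 0.321), -0.30 in hippocampus (adjusted p = 0.584) and -0.28 in cerebellum (adjusted p = 1). Without a filter 3 probes passed in cortex.

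The slope of the KO minus WT difference asked whether the effect of progranulin loss grows with age. ILMN_2614655 gained 0.10 per month in cortex (SE 0.018, adjusted p = 0.0118), 0.18 in hippocampus (SE 0.025, adjusted p = 0.000206) and 0.27 in cerebellum (SE 0.029, adjusted p = 2.11e-07). It was detected on no WT array, so its slopes and differences are taken against background and do not measure the full change. At 2 months its KO minus WT difference was 0.36 in cortex (adjusted p = 0.504), -0.03 in hippocampus (adjusted p = 0.997) and 0.26 in cerebellum (adjusted p = 0.871). At 18 months it rose by 2.10 in cortex (SE 0.24, adjusted p = 3.68e-07), 2.77 in hippocampus (SE 0.33, adjusted p = 4.69e-06) and 4.20 in cerebellum (SE 0.34, adjusted p = 3.25e-10), where it was detected on 3 of 3 KO and 0 of 3 WT arrays in each region. In hippocampus at 18 months it was 2.16 without KO replicate 3, 3.40 without KO replicate 2, and had adjusted p = 0.174 in a fit of those 2 groups alone. At 12 months it rose by 2.09 in hippocampus (adjusted p = 0.00524) and 2.96 in cerebellum (adjusted p = 1.01e-05), and differed by 0.63 in cortex (adjusted p = 0.631). In het mice it differed by 0.10 in cortex (adjusted p = 0.996), 0.09 in hippocampus (adjusted p = 0.951) and -0.0005 in cerebellum. Its cortex slope did not pass without background correction (0.033, adjusted p = 0.502) or without the 18-month arrays (0.059, adjusted p = 1). The slope passed limma's test for 2 probes in cortex (2 positive; 1010 at an unadjusted p under 0.05), 3 in hippocampus (3 positive; 466) and 31 in cerebellum (30 positive and 1 negative; 780). Without the 18-month arrays 0 passed in cortex (626 at an unadjusted p under 0.05) and 10 in cerebellum, and with a stricter filter 1 in cortex, 1 in hippocampus and 7 in cerebellum.

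**Figure D3:**
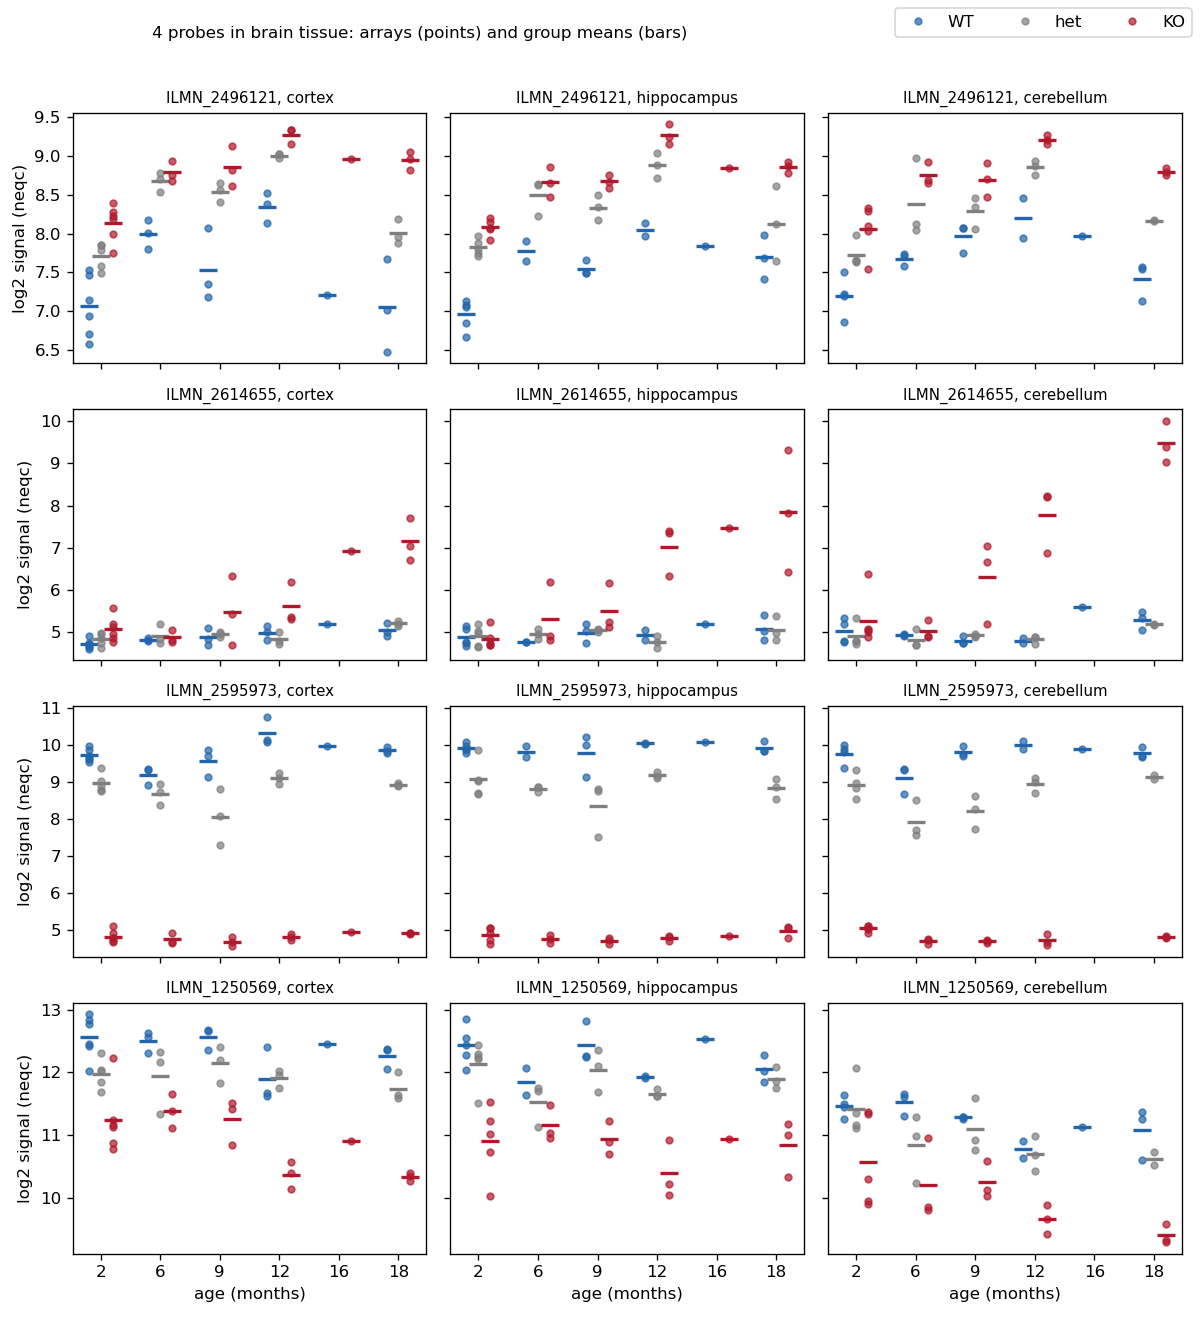
Log2 normalized intensity of probes ILMN_2496121, ILMN_2614655, ILMN_2595973 and ILMN_1250569 in cortex, hippocampus and cerebellum by age in months, with points for arrays, bars for group means, and WT in blue, het in gray and KO in red. ILMN_2614655 averaged 9.48 in KO cerebellum at 18 months against 5.28 in WT.

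Single ages showed few probes past limma's test besides the cerebellum at 6 months. At 2 months 36 passed in cortex (14 higher and 22 lower), 10 in hippocampus (3 and 7) and 31 in cerebellum (16 and 15). At 18 months 29 passed in cortex (26 and 3), 21 in hippocampus (19 and 2) and 69 in cerebellum (67 and 2). At 9 months the counts were 5, 4 and 7, and at 12 months 16, 16 and 33. At 6 months 3 passed in cortex, 1 in hippocampus and 494 in cerebellum (242 higher and 252 lower). That last count depended on which arrays were included: it was 1 without WT replicate 1 or KO replicate 2, 5 without KO replicate 3, 307 without WT replicate 3, 1131 without WT replicate 2 and 1283 without KO replicate 1, and all 3 WT mice were female. At 2 months counts in cortex were 21 to 92 with 1 replicate left out (62 without WT replicate 1, 92 without KO replicate 2 and 21 without KO replicate 6). In hippocampus they were 6 to 76 (76 without WT replicate 5, 25 without WT replicate 1, 21 without KO replicate 3, 16 without KO replicate 1 and 6 without WT replicate 3). In cerebellum they were 29 to 65 (65 without KO replicate 1, 56 without KO replicate 2 and 55 without WT replicate 1). At 18 months they were 13 to 22 in cortex (19 without WT replicate 1, 16 without WT replicate 2, 17 without KO replicate 1 and 13 without KO replicate 2). In hippocampus they were 4 to 20 (4 without KO replicate 3, 12 without KO replicate 2, 11 without WT replicate 1 and 10 without WT replicate 2).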

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

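The tests of microglia share, RNA integrity and label swap at 16 months, of choroid plexus cells at 4 months, and of a single array and sex in the cerebellum at 6 months were chosen only after the result was seen.

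Features that differed between KO and WT microglia at 16 months numbered 10988, against 8 at 4 months, and the interaction was significant for 4263. That fit takes a common spread for all groups. The log2 difference between arrays of a group had a scaled median absolute deviation of 0.565 to 1.28 in KO at 16 months and 0.383 to 0.508 at 4 months. In fits of each age alone 3449 features passed at 16 months and 26 at 4 months. With a replicate block 1957 passed for the interaction. Calls were not confined to dim features. Among features well above background on all arrays, 49.8% of the brightest of 4 equal bins passed limma's test and 34.9% of the dimmest. Dimmer features were not covered. Weak signal on the dimmer KO arrays was not excluded, because bright features pass more easily and a difference in scaling reaches them too. The share of rises was 64.6% among probes above background on all 15 arrays and 42.9% with a 75th percentile over probes detected on all arrays. A lower share of microglia was not excluded either. Markers of other cell types did not rise evenly, since 12 fell while 19 rose, but a changed mix of other cells could also give falls. With Grn above background on 0 KO arrays, a swap of labels between the groups was excluded. Lower RNA integrity in KO cannot be told apart, because the change correlated between 2 probes of a gene at 0.626 (0.591 to 0.660, 95% bootstrap interval), as for WT aging (0.6249, 0.575 to 0.667). An effect of progranulin loss in aged microglia stays open, and so do handling of the KO sort and the use of 2 WT replicates. Position on the slide, which differed between the genotypes, stays open too.

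Choroid plexus genes were higher in KO than in WT microglia at 4 months, by a median of 3.05. RNA of choroid plexus cells in the KO samples cannot be told apart from other causes, because the test of it restates the rise: 12 of 12 genes lay higher on every KO than on every WT array (2.86% by chance for each gene). The sort on CD11b and CD45 should remove such cells. Ttr, whose probe gave the highest signal of them, stood at 5.35 in WT and 7.71 in KO. An overall shift of the KO arrays was excluded, since 0% of 10000 random lists of like mean rose as far (highest median 0.58). No biological explanation was tested.

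In cerebellum at 6 months 494 probes differed between KO and WT, against 3 in cortex and 1 in hippocampus. A single array that stands apart was not excluded. Leaving out any of 3 arrays (WT replicate 1, KO replicate 2 or KO replicate 3) took the count below 50, to 1, 1 and 5, but each removal also costs power. The log2 difference of KO replicate 1 from replicates 2 and 3 had a scaled median absolute deviation of 0.404 and 0.467, against 0.216 between those 2. Among WT arrays it was 0.271 to 0.400. Without KO replicate 1 the count was 1283. The sex of the WT mice, all female, cannot be told apart, because the count was 210 without a sex term. An effect of progranulin loss at this age stays open.

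Other splits of the same samples into groups of the same sizes were counted. For microglia at 4 months, 1 of 35 splits reached the real count of 8 and the highest other split gave 7. That count includes Grn, whose call the genotype fixes, so chance was not excluded for the other calls. The few het calls given below may likewise include a Grn probe, which could not be named in brain. Over all ages chance was excluded for KO against WT in cortex (1 of 100 splits; real 124, highest other 1), hippocampus (1 of 100; real 88, highest other 1) and cerebellum, where 1 of 100 splits reached the real count and the highest other was 1. For het against WT, 1 of 100 splits reached the real count in cortex (real 5, highest other 1). In hippocampus 2 of 100 did (real 3, highest other 20) and in cerebellum 1 of 100 (real 2, highest other 1). Each het count includes ILMN_2595973, which was detected on no KO array, so chance was not excluded for the other het calls. For the slope, chance was excluded in hippocampus (2 of 100, real 3, highest other 17). It was also excluded in cerebellum (2 of 100, real 31, highest other 67) and not in cortex (5 of 100, real 2, highest other 5). At 2 months chance was not excluded in cortex (9 of 100; real 36, highest other 8.69 times as many), hippocampus (53 of 100; real 10, highest other 969) or cerebellum (39 of 100; real 31, highest other 1148). Those high splits, the highest ones for the het and slope results in hippocampus and for the slope in cerebellum, and the highest one for the difference between hippocampus and cerebellum given next, point to a structure of the samples, which was not tested. Chance was not excluded for the difference of the KO effect between hippocampus and cerebellum (4 of 50; real 1, highest other 132). For hippocampus and cortex (50 of 50; real 0, highest other 0) and cortex and cerebellum (50 of 50; real 0, highest other 1) every split reaches a count of 0, so the splits say nothing about chance. With 10 splits the 3 against 3 comparisons have too few for a share under 0.05: cortex at 18 months (1 of 10; real 29, highest other 0), hippocampus at 18 months (1 of 10; real 21, highest other 1), cerebellum at 18 months (1 of 10; real 69, highest other 0) and cerebellum at 6 months (1 of 10; real 494, highest other 82).

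Effects also differed between groups by direct tests. Of 73 named genes that passed at 16 months, 43 had a change that differed from that at 4 months, against 4263 of all 31922 features; these genes were chosen for their 16-month values, which the interaction reuses, so a high share is built in. By limma's test the KO minus WT difference changed with age for 2 probes in cortex, 3 in hippocampus and 31 in cerebellum. The KO effect of 1 probe differed between hippocampus and cerebellum. The splits above did not exclude chance for the cortex slope or for that difference between regions.

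Single replicates stood apart from their group in 12 groups (6.09% of those tested) by Dixon's ratio (gap over range), and chance gives about 1 in 20. Among WT microglia at 4 months, Fdft1 was -1.23 in replicate 1 against -1.50 to -1.46 in the others (ratio 0.856), Dusp1 4.72 in replicate 2 against 5.19 to 5.25 (0.884) and Dnase1l2 1.48 in replicate 3 against 1.2 to 1.24 (0.875). Among KO microglia at 16 months, Bst2 was 5.86 in replicate 2 against 5.10 to 5.14 (0.944) and Ccl4 4.94 in replicate 4 against 4.20 to 4.30 (0.869). Replicate 1 of that group had Fabp5 at 4.11 against 5.30 to 5.41 (0.914) and Clec5a at -1.59 against -3.40 to -3.22 (0.898). In het cerebellum at 2 months replicate 3 had ILMN_2496121 at 7.98 against 7.63 to 7.66 (0.934) and ILMN_2614655 at 5.34 against 4.73 to 4.80 (0.876). ILMN_2614655 was 6.38 in replicate 4 of KO cerebellum at 2 months against 4.89 to 5.07 (0.877). ILMN_1250569 was 11.51 in replicate 5 of het hippocampus at 2 months against 12.21 to 12.44 (0.759) and 12.24 in replicate 3 of KO cortex at 2 months against 10.78 to 11.24 (0.683).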

How the results depend on the processing

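Alternatives moved counts more than directions, and the cause was not tested. Of the named gene results past the threshold, 51.8% kept direction and threshold in every alternative run on them; of their 3110 alternative values 369 missed the threshold and 6 reversed. The normexp alternative on the median signal, the 4 WT arrays at 16 months as separate replicates, the lower floor and all alternatives for cerebellum at 6 months were chosen after the data had been seen. A block for the bead chip was not run. For microglia at 4 months (8), quantile normalization gave 2, normexp 2, probes above background on all 15 arrays 0 (751 at an unadjusted p under 0.05 by limma), the 2 groups alone 26, separate WT arrays 16 and 1 replicate left out 3 to 10. At 16 months (10988) the 2 groups alone gave 3449. The interaction (4263) gave 6818 with separate WT arrays and 2435 to 5653 with 1 replicate left out. WT aging (1106) gave 597 above background on all arrays, 3546 with separate WT arrays and 329 to 3768 with 1 replicate left out. The 22 list calls of camera became 1 with an estimated correlation.

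A replicate block gave 1 at 4 months, 8471 at 16 months, 1957 for the interaction and 433 for aging. With the block, adjusted p at 16 months was 0.0415 for C1qb, which passed, and 0.0642 for Pvalb, 0.0676 for S1pr3, 0.0508 for Vim, 0.0617 for Esam, 0.0859 for Adora2a and 0.0666 for Nkg7, which did not. At 4 months it was 0.312 for Apoe, 0.28 for Npr3, 0.214 for Zfp459 and 0.214 for Acvr1c. For the interaction it was 0.0508 for Siglech, 0.0681 for Isg15, 0.0889 for Fabp5, 0.0661 for Map2, 0.0586 for Mobp, 0.0648 for Itm2a, 0.135 for Gpr6, 0.0705 for Cd79b, 0.147 for Atf4 and 0.0955 for Grm8. For aging it was 0.126 for Atp6v1a, 0.0541 for Sox9, 0.0744 for Ppp1r1b, 0.0615 for F13a1, 0.0551 for Cd79b, 0.0513 for Cxcl13, 0.0501 for Ccl8, 0.06 for Dnase1l2, 0.0911 for Crygs, 0.0918 for Hhip, 0.0869 for Meis2 and 0.0984 for Ppp1r12a. Camera gained 3 list calls with it: cell cycle at 4 months, disease-associated microglia for the interaction and cytokine and NF-kB for aging. The block changed no other call of a named gene or list.

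Reversed values were few. C1qc at 4 months was -0.064 with quantile normalization, -0.0049 with a 75th percentile over detected probes, -0.025 with normexp and -0.095 to 0.205 with 1 replicate left out. Mobp was 1.54 at 16 months and 1.36 for the interaction on the probe kept by the filter on all 15 arrays. With 1 replicate left out C1qa ran from -1.76 to 0.030 and C1qb from -2.004 to 0.055 at 16 months. For the interaction C1qa ran from -1.37 to 0.42, C1qb from -1.78 to 0.28 and Camk2a from -3.88 to 0.74. For aging C1qa ran from -1.50 to 0.29, C1qb from -1.48 to 0.58 and C1qc from -0.70 to 0.046, and Fam13c ran from -2.05 to 6.58 at 16 months.

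In brain tissue the stricter detection filter gave 1 for the slope in cortex (2), 23 for cortex at 2 months (36), 1 for the slope in hippocampus (3), 68 for KO in cerebellum over ages, 7 for its slope (31), 18 there at 2 months (31), 30 at 18 months (69) and 823 at 6 months (494). Without a filter het cortex gave 3 (5) and cerebellum at 2 months 76. Without background correction cortex at 2 months gave 23, cerebellum at 6 months 764 and cortex minus cerebellum 1 (0). The 2 groups alone gave 2 in cortex, 4 in hippocampus (10) and 2 in cerebellum at 2 months, 13 in cortex (29) and 6 in hippocampus (21) at 18 months, and 3 in cerebellum at 6 months. Without the 18-month arrays the slope gave 0 in cortex (626 at an unadjusted p under 0.05 by limma) and 10 in cerebellum; without the 12-month arrays KO over ages gave 46 in hippocampus (88) and 61 in cerebellum. Without a sex term cerebellum at 6 months gave 210. With 1 replicate left out the counts were 21 to 92 in cortex, 6 to 76 in hippocampus and 29 to 65 in cerebellum at 2 months, 13 to 22, 4 to 20 and 46 to 66 at 18 months, and 1 to 1283 in cerebellum at 6 months.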

Other observations

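The test of genes near Grn and the comparisons of levels in this part were chosen only after the results were seen.

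Cd74, of the antigen presentation list, rose by 4.44 between 4 and 16 months in WT and differed by -4.41 between KO and WT at 16 months, which put KO at 16 months (-0.71) near WT at 4 months (-0.74) and away from WT at 16 months (3.70). The 2 differences share the 2 WT replicates of 16 months, so they are not independent, and opposite signs arise from that sharing alone when those replicates stand high. Levels at 4 and 16 months also come from different slides and kinds of processed signal. Their closeness therefore does not show that KO at 16 months resembled WT at 4 months. The antigen presentation list was not called for WT aging (camera adjusted p = 0.41).

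Choroid plexus genes stood higher in each of the later or KO groups. Kl was -3.17 in WT and 0.97 in KO at 4 months, and 3.92 and 6.33 at 16 months, and Kcnj13 was -0.21, 3.06, 4.60 and 7.80 in the same groups. Border macrophage genes rose with age in WT by a median of 5.22 relative to all features. In both comparisons between ages, age and slide cannot be told apart.

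Sex-linked genes differed within groups whose labels give no sex. Xist, transcribed from the inactive X, was 1.42 and 1.36 in WT replicates 1 and 2 at 4 months and -4.22 and -4.94 in the others, while the Y-linked Ddx3y was -4.94 in the former and 3.20 and 3.08 in the latter. KO replicate 1 at 4 months had both (1.28 and 1.35), and KO replicate 3 at 16 months had Xist at 0.46 and Ddx3y at -4.94.

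Variants carried along with the targeted locus may affect genes next to Grn. This was tested in microglia only, since the bead array probes had no gene names. Of the 40 nearest measured genes 3 (7.5%) had an unadjusted p under 0.05 at 4 months, against 1038 of 17754 others (5.85%), with a one-sided Fisher exact p of 0.417 and 0 past limma's adjusted threshold, which leaves the question open.

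Probes of the same gene disagreed for some genes. Of 837 genes with over 1 probe past the threshold at 16 months, 64 (7.65%) had probes that moved in opposite directions, as did 8 of 210 (3.81%) for the interaction and 0 of 55 for WT aging.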
